A study of Homo sapiens with 24 samples.

How the data were processed

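Per the labels, poly(A)-selected, strand-marking RNA sequencing libraries had been made from the acute myeloid leukemia lines MOLM14 and MV4-11 after 24 h with DMSO or with gilteritinib, crenolanib or AC220 at 2 nM. Per the labels' protocols, RNA was isolated with genomic DNA depletion and read as 150-bp pairs on a NextSeq 500 or a NovaSeq6000. The labels do not say which sample was read on which instrument. Histone mRNAs, which mostly lack a poly(A) tail, stood at a median of 107 times their replicate 2 level in DMSO of MV4-11 replicate 1, so that selection may not hold for this library. STAR 2.4.0, DESeq2 1.1.0 and the genome build hg19 are named in the submitters' processing notes, without their roles. Whether the counting used strand is not given in the sources used here, so reads of overlapping and antisense genes were taken as not separable. The labels say that the experiments were done in triplicate. Nothing says that the 3 samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

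The deposited files were 18 tables of the authors' own comparisons, 3 for each inhibitor in each line, each holding DMSO and 1 inhibitor. Per the file headers, the deposited levels were log2 values of a normalized count or of FPKM, and the log2 fold change and its standard error were the authors'. The deposited mean count of each gene, a signal over the libraries of its table, and the authors' q-value were read to learn how each table was made. In the authors' deposited tables of MOLM14, q-values called 0 genes for each inhibitor in the tables of replicate 1. They called 3029 to 4056 genes in the tables numbered 2 and 4424 to 4714 in those numbered 3. In the authors' deposited tables of MV4-11, they called 28 to 58 genes in the tables numbered 1, 0 in those numbered 2 and 0 to 100 in those numbered 3.

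The numbers on the tables did not mean 1 replicate each. In MOLM14, the tables numbered 1 held 1 library per arm as normalized counts, and those numbered 2 held the means of libraries 1 and 2. The MOLM14 tables numbered 3, in FPKM, included a further library that could not be taken apart, so it was not analysed here. In MV4-11, the tables numbered 1 and 2, in FPKM, were taken to hold 1 library per arm, since nothing in them shows more. Those numbered 3 held the linear mean of library 2 and a further library. Library 2 of MOLM14 and library 3 of MV4-11 were therefore computed by subtraction. On simulated tables, the subtraction returned the hidden log2 ratio with a median absolute error of 0.005 in MOLM14 and 0.00587 in MV4-11. Those tables were built with the averaging that the subtraction assumes and with a known scale, so this error covers rounding alone. In the real tables the averaging was inferred and the scale estimated, and the error does not test these. The MV4-11 tables numbered 1 use other gene models than the rest, with many loci that carry no gene name. 2 tables stop at 22000 rows, which left 3320 MOLM14 genes without an AC220 value in library 2 and 2677 MV4-11 genes without a crenolanib value in library 3. Genes that could not be taken apart, 42 in MOLM14 and 86 in MV4-11, were left out. This left 13018 and 12682 genes with values. The DMSO columns of the tables of different inhibitors held the same libraries (correlation across genes of at least 0.9989), so all comparisons of a line share their controls.

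Depth could be read only from the steps between low values in the MOLM14 tables of replicate 1, where 1 read had a fixed worth. The steps of a table were not assigned to its arms, so they only bound the libraries within 21.0 to 27.9 M reads. The shared DMSO library was at 22.5 to 23.6 M reads in the tables of gilteritinib and AC220. The FPKM tables gave no depth, so their precision rests on the spread between replicates alone. Count models were not run, since no table holds counts of all libraries.

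The design had been fixed before the data were examined, with a branch for tables normalized on their own, which was the one taken. In it, limma (3.58.1, R 4.3.3) was fitted to the within-replicate differences of log2(value + 1) between inhibitor and DMSO, with a trend of the spread with level. The replicate was the unit for the mean response and for the difference between lines. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. A fit of all libraries of a line with the replicate number as a block had been run, and its results seen, before this branch was taken, and is given among the alternatives. Genes needed a value of at least 10 normalized counts (MOLM14) or 1 FPKM (MV4-11) in 2 libraries, which left 12958 and 12109. Each library's median log2 ratio was set to 0. It had been at most 0.02 away.

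Single inhibitors were tested with the spread pooled over the 3 inhibitors. There each difference between an inhibitor and a DMSO library was a unit, although the 3 of a replicate share 1 DMSO library. The p-values of single inhibitors may therefore be too small. The response common to the inhibitors was the mean over inhibitors within each replicate, with 2 replicates in MOLM14 and 3 in MV4-11. Differences among inhibitors were tested within replicates by a joint F test, and the difference between lines on the mean responses of the replicates, over 10908 genes measured in both. p-values were adjusted by the Benjamini-Hochberg method and called at 0.05. The replicate numbers were taken to pair the samples, since each table sets an inhibitor against DMSO libraries of the same number or numbers. Deviations from the treatment means also correlated between same-numbered libraries of MV4-11 (r from 0.830 to 0.985). The other gene models of the tables of replicate 1 may raise this correlation, so it does not show paired cultures. In MOLM14, where only 2 replicates enter, such a correlation is partly built in (0.481 to 0.900).

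On simulated data with the spread of these libraries, the mean response recovered 53% of genes changed by 1 on the log2 scale and 91% of those changed by 2 in MOLM14, and 97% and 100% in MV4-11. Single inhibitors recovered 24% to 25% and 64% to 70% in MOLM14, and 87% to 93% and 100% in MV4-11. The joint test of inhibitor differences recovered 90% and 100% in MOLM14 and 95% and 100% in MV4-11. The test between lines recovered 60.5% and 96.1%. In these runs the noise of each gene was drawn on its own from spreads that limma had already drawn toward a common trend. This favours the refit, so the recovered shares may be too high. Differences in response between the MV4-11 replicates that many genes share were not simulated.

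Before the data were examined, 28 gene lists were fixed. They covered creatine synthesis and use, arginine, polyamine and methyl-donor metabolism, STAT5 targets, MAPK pathway output, FOXO targets, ribosome biogenesis, G1/S and DNA replication, and G2/M and mitosis. They also covered glycolysis and lactate export, ATF4 targets and serine synthesis, cholesterol synthesis, oxidative phosphorylation, heme and iron handling, BCL2 family, p53 targets, interferon response, NF-kB and inflammatory cytokines, and receptor tyrosine kinases and cytokine receptors. Differentiation was covered by monocyte and macrophage markers, granule and progenitor markers, and the HOXA-MEIS1 programme. Other cell types were covered by lymphoid, erythroid and megakaryocyte, and epithelial and stromal markers. RNA and culture quality were covered by heat shock and immediate stress, mitochondrially encoded mRNAs, replication-dependent histones and cytosolic ribosomal proteins. The lists were tested by the camera statistic of limma with a preset correlation of 0.01, and again with an estimated correlation. The estimated correlation left the test few degrees of freedom, so a list that did not pass it was not shown to be unmoved. The rotation test fry was run on genes measured in every library. Fry took single libraries with the replicate as a block, so the inhibitor libraries of a replicate were separate units. Its p-values may therefore be too small. The mitochondrial list had 0 members in the tables and was not tested.

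The rule for naming genes was also fixed beforehand. For the mean response of each line, it took the 10 largest rises and falls among called genes in the top 60% by level that moved the same way in every pair. It took the top 3 each way for each inhibitor and the top 5 each way for differences between inhibitors or lines. GATM, the creatine list and FLT3 were named throughout, with the 4 members of every other list that had the smallest adjusted p. Clone names were passed over.

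Similarity of responses was set beside 50 simulations of unchanged inhibitor libraries against the same controls. In these, the DMSO libraries were given the spread seen between inhibitors. Gene symbols, transcript GC content and length came from GENCODE, for 97.1% of the MOLM14 and 94.1% of the MV4-11 genes. Coordinates are those of the authors' tables on hg19. Data were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. The alternatives were the block, the pseudocount, the filter, quantile normalization, limma without its trend, a fold threshold, only the compared libraries, each replicate or library left out, and other ways of taking the tables apart.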

Results

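Gene expression was measured by RNA sequencing in MOLM14 and MV4-11, human acute myeloid leukemia cell lines that carry an internal tandem duplication (ITD) of the receptor tyrosine kinase gene FLT3. Per the labels, the mutation is heterozygous in MOLM14 and hemizygous in MV4-11. Each line was kept for 24 h in the vehicle DMSO or in 2 nM of gilteritinib, crenolanib or AC220 (quizartinib), small-molecule inhibitors of FLT3. There were 3 samples in each group and 24 in all. The series concerns the transcriptional signature of FLT3-ITD and the place of creatine synthesis in it. The comparisons ask which transcripts each inhibitor changed in each line, whether the 3 inhibitors differed, and whether the lines differed. Values of their own could be had for 2 replicates of MOLM14, in normalized counts, and for 3 replicates of MV4-11, in FPKM of unknown depth. The MOLM14 libraries of replicate 1 lay within bounds of 21.0 to 27.9 M reads. Levels were normalized separately in each table, so tests ran on ratios within tables. Adjusted p-values are limma's, over all genes tested unless stated.

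GATM, which encodes the enzyme of the committed step of creatine synthesis, fell in MOLM14. Its mean log2 fold change over the 3 inhibitors was -2.81 ± 0.43 (SE, n = 2 replicates, adjusted p = 0.000425), and it was lower in 6 of 6 pairs of inhibitor and DMSO libraries. GAMT, which methylates the product of GATM to creatine, also fell in MOLM14, by -1.22 ± 0.29 (SE, n = 2, adjusted p = 0.00618, lower in 6 of 6 pairs). In MV4-11, GATM was lower in 9 of 9 pairs with a mean of -0.99 ± 0.23 (SE, n = 3), which did not pass (adjusted p = 0.303). It passed in the fit of all libraries with the replicate as a block, given below, where inhibitor libraries of a replicate are separate units. GAMT was lower in MV4-11 in 9 of 9 pairs at -1.76 ± 0.23 (adjusted p = 0.0891). GAMT passed in MV4-11 for gilteritinib alone (log2 fold change -1.99, adjusted p = 0.0455), in the test that pools the spread over inhibitors with shared controls.

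GATM (hg19, chromosome 15, 45653321 to 45670980 or, in some tables, to 45672707) stood at 160 ± 21.3 normalized counts in MOLM14 with DMSO (SD, n = 2). It stood at 27.4 ± 12.1 with gilteritinib, 19.2 ± 11.1 with crenolanib and 26.7 ± 19.1 with AC220. In MV4-11 with DMSO, GATM was at 0.763, 8.55 and 2.94 FPKM in replicates 1, 2 and 3, and GAMT (chromosome 19, 1397024 to 1401569) at 5.13, 82.3 and 19.3 FPKM. The 3 other measured members of the creatine list did not pass in either line. The creatine transporter gene SLC6A8 (chromosome X, from 152953751) was at -0.15 in MOLM14 and 0.19 in MV4-11. The creatine kinase genes CKB (chromosome 14, 103985994 to 103989196) and CKM were at 0.30 and 0.01 in MOLM14 and at 0.01 and 0.09 in MV4-11. Thus 2 of 5 members fell in MOLM14, and 2 when adjusted over the list alone. In MV4-11, 0 fell over all genes and 2 when adjusted over the list alone (GATM 0.0163, GAMT 0.0021). The list was built around the gene in the series title, so neither count is independent evidence. Against other genes the list did not stand out by the camera test in MOLM14 (adjusted p = 0.318, and 0.474 with an estimated correlation) or MV4-11 (0.316, and 0.726 with an estimated correlation). Its median and mean in MV4-11 were 0.01 and -0.49.

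In the authors' deposited tables, the q-values of GATM in MOLM14 were 0.000114, 8e-06 and 9.9e-05 for gilteritinib, crenolanib and AC220 in the tables numbered 2. In the authors' deposited tables of MV4-11, GATM passed for crenolanib in the table numbered 3 (q = 0.0425) and in no other. GAMT passed there for gilteritinib (q = 0.0153) and crenolanib (q = 0.0112) in the tables numbered 3, which hold means of libraries 2 and 3, and in no other. FLT3 itself (chromosome 13, 28577410 to 28674729) rose in MOLM14, with a mean of 0.65 (adjusted p = 0.00903; 0.86 with gilteritinib, 1.02 with AC220 and 0.06 with crenolanib), and was at -0.56 in MV4-11 (adjusted p = 0.246). Without MV4-11 replicate 1, GATM in MV4-11 stood at -1.31 and passed (limma adjusted p = 0.000222). It did not pass without replicate 2 (-0.73, adjusted p = 0.163) or without replicate 3 (-0.92, adjusted p = 0.207).

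**Figure D1:**
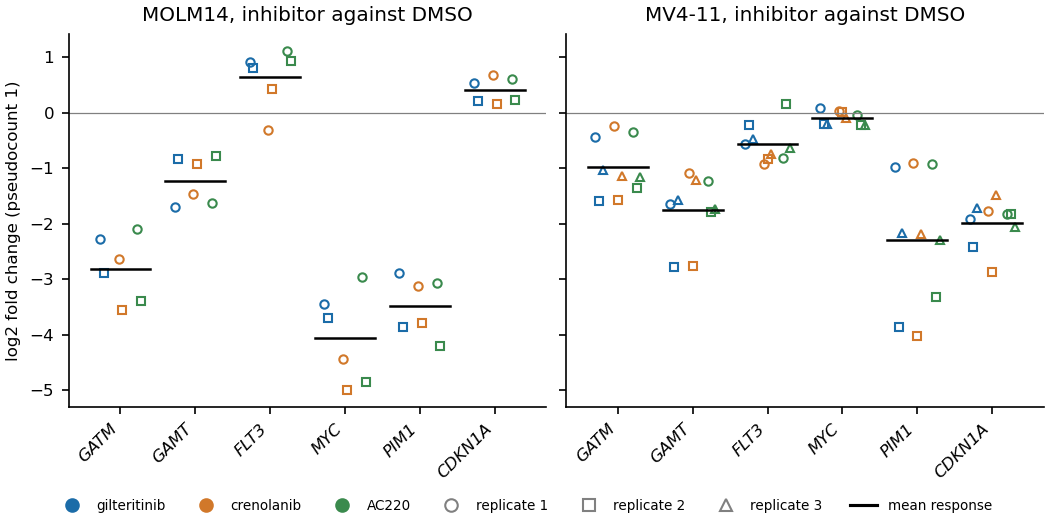
Log2 fold changes against the DMSO library of the same replicate for GATM, GAMT, FLT3, MYC, PIM1 and CDKN1A in MOLM14 and MV4-11, with a point per inhibitor and replicate and a black line for the mean response. GATM and GAMT lie below 0 at every point, MYC lies below 0 in MOLM14 (mean -4.07) and near 0 in MV4-11 (mean -0.09), and CDKN1A lies below 0 in MV4-11 alone (mean -1.98).

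The largest falls in MOLM14 under the naming rule were those of SLC7A5, a transporter of large neutral amino acids (-4.75 ± 0.28, SE, n = 2), NME1, a nucleoside diphosphate kinase (-4.08), the transcription factor MYC (-4.07 ± 0.22) and PSAT1 of serine synthesis (-4.05). The arginine transporter SLC7A1 (-3.89), the spermidine synthase SRM (-3.59), the kinase PIM1 (-3.49), the asparagine synthetase ASNS (-3.43), the metal transporter SLC39A14 (-3.38) and RRP12 of ribosome assembly (-3.36) followed. The largest rises were those of the metalloprotease-disintegrin ADAM28 (3.96 ± 0.41), the collagen COL24A1 (3.83), YPEL3 (3.64), the pro-apoptotic BH3 protein BMF (3.30) and the histone HIST1H2AC (3.24). TP53INP1 (3.09), the cholesterol exporter ABCA1 (3.07), the cannabinoid receptor CNR2 (3.05), the scavenger receptor CD36 (2.95) and the autophagy protein GABARAPL1 (2.67) followed. All 20 moved the same way in every pair measured (6, or 5 for genes without an AC220 value in replicate 2), with adjusted p-values between 1.22e-06 for MYC and 4.84e-05 for ABCA1.

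Targets of the signalling pathways downstream of FLT3 moved together in MOLM14. Of 14 measured genes of MAPK pathway output, 12 fell and 0 rose, among them the ETS factors ETV4 (-6.99) and ETV5 (-6.05), the feedback inhibitor SPRY2 (-4.01) and the AP-1 factor FOSL1 (-4.55). The list was called with a preset correlation (adjusted p = 7.21e-07), not with an estimated correlation (adjusted p = 0.174). Of 13 STAT5 targets, 8 fell and 0 rose, including MYC, PIM1, CISH (-1.67) and the cyclin CCND3 (-1.07). Their adjusted p was 0.000319 with the preset and 0.174 with an estimated correlation. Of 16 FOXO targets, 12 rose and 1 fell, among them the PI3K inhibitor PIK3IP1 (2.64), the ubiquitin ligase component FBXO32 (2.29), the cyclin CCNG2 (2.03) and TXNIP (1.54). That list had adjusted p = 7.3e-05 with the preset and 0.174 with an estimated correlation.

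Genes of ribosome production and the cell cycle fell in MOLM14. Of 24 ribosome biogenesis genes, 23 fell, including BOP1 (-3.02), MYBBP1A (-2.99), RRS1 (-2.97) and NOLC1 (-2.44), with adjusted p = 3.83e-17 with the preset and 0.174 with an estimated correlation. By contrast, 0 of 22 cytosolic ribosomal protein genes passed, with RPL37 at 0.25 and RPL11 at 0.22 (adjusted p = 0.435 for the list, and 0.888 with an estimated correlation). All 24 measured G1/S and replication genes fell, such as the cyclin CCNE2 (-3.21), the ribonucleotide reductase subunit RRM2 (-2.67), the helicase subunit MCM6 (-2.59) and UHRF1 (-2.05). For these the adjusted p was 2.38e-12, and 0.418 with an estimated correlation. Of 20 G2/M genes 17 fell, by less, including CCNA2 (-1.41), UBE2C (-1.35), CDC20 (-1.25) and TPX2 (-1.08), with adjusted p = 2.99e-06, and 0.474 with an estimated correlation.

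Metabolic genes fell in MOLM14 in several groups. Of 22 ATF4 targets and serine synthesis genes, 17 fell, including SLC7A5, PSAT1, the cystathionine synthase CBS (-4.74) and the dehydrogenase of serine synthesis PHGDH (-3.08), with adjusted p = 4.38e-09, and 0.474 with an estimated correlation. Of 15 genes of arginine, polyamine and methyl-donor metabolism, 10 fell and 2 rose. Ornithine decarboxylase, ODC1, fell (-2.69), and SAT1, which acetylates polyamines for export, rose (2.16), with adjusted p = 0.000738 for the list, and 0.174 with an estimated correlation. Of 20 glycolysis genes 13 fell and 1 rose, with the lactate transporter SLC16A1 at -2.85, the glucose transporter SLC2A3 at -2.55, LDHA at -2.20 and TPI1 at -1.48 (adjusted p = 4.4e-06, and 0.174 with an estimated correlation). Of 19 cholesterol synthesis genes 16 fell, including DHCR7 (-2.48), SQLE (-1.57) and HMGCS1 (-1.22), with adjusted p = 4.4e-06, and 0.174 with an estimated correlation. Of 20 oxidative phosphorylation genes 13 fell, by about 1 or less, as CYC1 (-1.20), NDUFA9 (-1.07), COX6C (-0.98) and COX5A (-0.90) did, with adjusted p = 0.000139, and 0.474 with an estimated correlation. In the heme and iron list, 3 genes rose and 3 fell of 14. Heme oxygenase HMOX1 rose by 4.75 and ferritin FTH1 by 1.37, while the transferrin receptor TFRC (-2.52) fell (adjusted p = 0.572, and 0.629 with an estimated correlation).

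More monocyte markers, HOXA-MEIS1 genes, interferon genes and receptors rose than fell in MOLM14, while granule and NF-kB genes were mixed. Of 12 monocyte and macrophage markers, 6 rose and 1 fell, with the receptor CSF1R at 2.49, CD68 at 1.93, TLR4 at 1.34 and FCGR1A at -1.14 (adjusted p = 0.00572, and 0.474 with an estimated correlation). Of 12 genes of the HOXA-MEIS1 programme, 8 rose and 0 fell, including HOXA3 (1.95), HOXA5 (1.19), MEIS1 (1.04) and JMJD1C (0.94), with adjusted p = 0.000295, and 0.174 with an estimated correlation. Of 20 interferon response genes, 11 rose and 0 fell, including IFIT2 (3.18), IFIT3 (2.33), OAS1 (2.10) and STAT2 (2.02), with adjusted p = 3.81e-05, and 0.474 with an estimated correlation. Of 14 receptors, 7 rose and 2 fell, with IL10RA at 2.25, AXL at 1.83 and FGFR1 at -1.88 (adjusted p = 0.00572, and 0.474 with an estimated correlation). Granule and progenitor markers went both ways (2 of 11 rose, 3 fell), with KIT at 1.78, CEBPA at 0.57, MPO at -1.27 and PRTN3 at -1.82 (adjusted p = 0.942, and 0.944 with an estimated correlation). So did NF-kB and inflammatory genes (5 of 13 rose, 3 fell), with BIRC3 at 1.39, NFKBIA at 0.87, CCL2 at -4.53 and TNF at -5.19. Their median was 0.26 and their mean -0.35 (adjusted p = 0.751, and 0.798 with an estimated correlation).

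Of 15 p53 targets in MOLM14, 7 rose and 1 fell, including TP53INP1, ZMAT3 (1.16), XPC (0.74) and, in the other direction, AEN (-1.24), with adjusted p = 0.0104, and 0.474 with an estimated correlation. Of 13 BCL2 family genes 1 rose, BMF, and 4 fell, including BCL2 itself (-1.56), PMAIP1 (-1.52) and BID (-1.33). Their median was 0.07 and their mean -8.6e-05 (adjusted p = 0.920, and 0.944 with an estimated correlation). Of 8 replication-dependent histone genes, 7 rose, including HIST1H2BD (3.10), HIST2H2BE (2.71) and HIST1H1C (2.49). Their adjusted p was 1.55e-05, and 0.239 with an estimated correlation. These mRNAs mostly lack a poly(A) tail, so poly(A)-selected libraries measure a part of them. Of 14 heat shock and stress genes 8 fell, including the chaperones HSPE1 (-2.65), HSPA8 (-2.37), HSPD1 (-2.09) and HSPH1 (-1.69), with adjusted p = 0.000621, and 0.474 with an estimated correlation. Among markers of other cell types, PECAM1 rose (1.53), and KRT18 (-0.40), KRT8 (0.39), NKG7 (0.35) and EPOR (-0.21) did not pass. The epithelial and stromal list had adjusted p = 0.337, and 0.474 with an estimated correlation, and the lymphoid and erythroid lists had 1 measured member each.

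In all, 2534 genes rose and 2896 fell in MOLM14 in the mean response among 12958. Of 25 lists, 18 were called with the preset and 0 with an estimated correlation. The latter test had few degrees of freedom in every comparison, so its 0 does not show that the lists were unmoved. Adjusted over the list alone, 9 STAT5 targets, 24 ribosome biogenesis, 14 glycolysis, 18 ATF4, 14 oxidative phosphorylation and 9 heat shock genes fell, 8 p53 targets rose and 3 BCL2 family genes fell, with the other counts as above. The rotation test fry asks whether a list's genes move 1 way and not whether they exceed other genes. It called 19 of the 25 lists, creatine among them (adjusted p = 0.0147), with the inhibitor libraries of a replicate as separate units. With only 2 replicates the test leans on the spread shared across genes, and with either replicate left out there was no test.

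**Figure D2:**
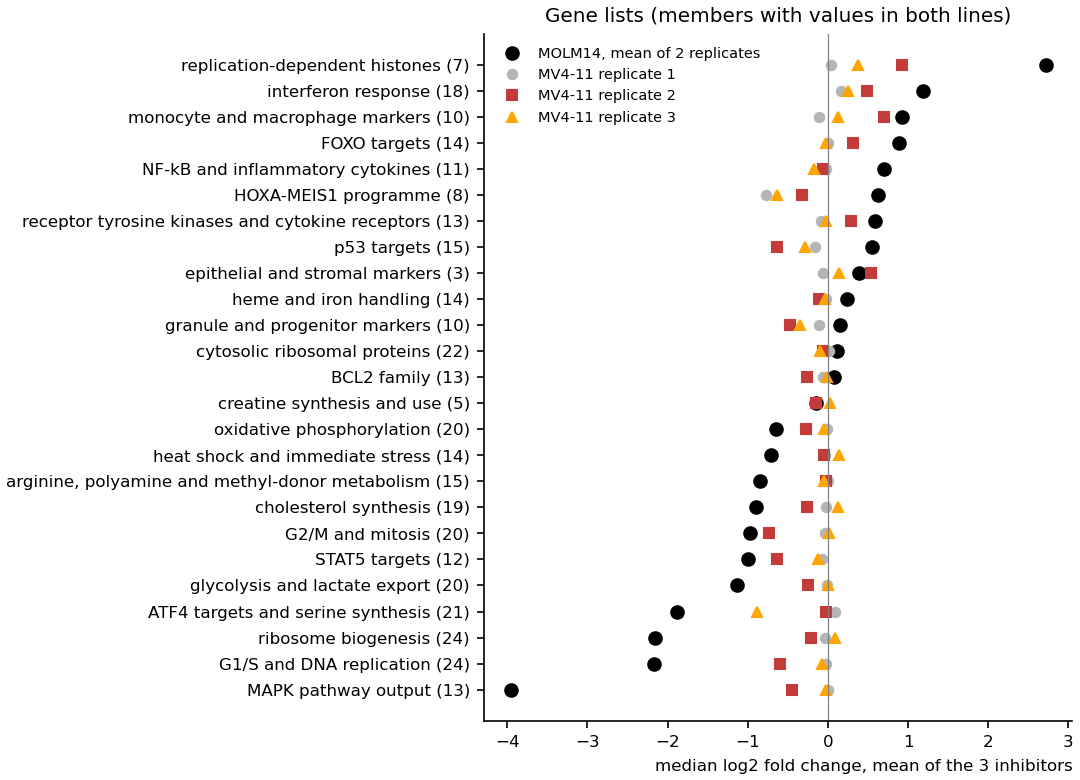
Median log2 fold change of each gene list for the mean of the 3 inhibitors, in MOLM14 and in replicates 1, 2 and 3 of MV4-11. MAPK output stood at -3.95 in MOLM14 and at -0.00, -0.45 and -0.02 in the MV4-11 replicates, over the 13 members measured in both lines.

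Each inhibitor alone gave the same leading genes in MOLM14. SLC7A5 and NME1 were among the 3 largest falls, and ADAM28, COL24A1 and YPEL3 the 3 largest rises, with each inhibitor, and PSAT1 (gilteritinib, AC220) or MYC (crenolanib) completed the falls. COL24A1 rose by 3.80, 3.85 and 3.83 with gilteritinib, crenolanib and AC220 (adjusted p = 0.00189, 0.00131 and 0.00214), and MYC fell by 3.58, 4.72 and 3.91. Gilteritinib raised 2486 genes and lowered 2653, crenolanib 2661 and 2776, and AC220 2119 and 2360. Without the replicate as a block the totals of 5139, 5437 and 4479 were 3115, 3448 and 2435. They were 623 without the gilteritinib library of replicate 1 (2662 without that of replicate 2), 885 without the crenolanib library of replicate 1 (2560) and 808 without the AC220 library of replicate 1 (641). Lists were called with the preset correlation 17, 16 and 18 times of 25, and 0 times with an estimated correlation.

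No gene passed the joint test of differences among the 3 inhibitors in MOLM14 by limma, the only tool that these units allowed (0 at an adjusted p under 0.05, 802 at an unadjusted p under 0.05). The 0 depended on the settings, with 46 genes without a filter, 77 with a stricter one, 6 with quantile normalization and 20 without the gilteritinib library of replicate 2. FLT3 had an unadjusted p of 0.00477 and an adjusted p of 0.549. It was at 0.86 with gilteritinib, 0.06 with crenolanib and 1.02 with AC220, and gilteritinib exceeded crenolanib by 0.80 (95% interval 0.32 to 1.28). For GATM the difference of gilteritinib and crenolanib was 0.52 (95% interval -0.08 to 1.11), and for GAMT -0.06 (-0.37 to 0.24). For the median gene the 95% interval of a difference between inhibitors reached 0.22 to 0.24 on either side, so smaller differences were not excluded. As lists, cholesterol synthesis genes were higher with gilteritinib than with AC220 (median 0.25, adjusted p = 6.53e-21, and 0.189 with an estimated correlation). G2/M genes were lower with gilteritinib than with crenolanib (median -0.28, adjusted p = 8.88e-14, and 0.507 with an estimated correlation). The fold changes of the inhibitors correlated across genes at 0.961 to 0.973, against 0.454 to 0.499 in simulations of unchanged groups with the same shared controls. Their covariances were 1.02 to 1.06, against 0.0175 to 0.0179 in those simulations. Gilteritinib and crenolanib shared 2484 falls and 2306 rises, where independent lists would share 568 and 511. With 1 DMSO library per replicate the controls could not be split, so part of the excess may come from them. The simulations gave DMSO the spread seen between inhibitors. A larger spread of DMSO would raise the simulated correlations and covariances, so how much of the excess is response was not settled.

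In MV4-11, 29 genes fell in the mean response by limma and 0 rose, against 1036 and 461 at an unadjusted p under 0.05. The neutrophil elastase gene ELANE fell by 2.02 (SE 0.20, n = 3, adjusted p = 0.0473), the cyclin-dependent kinase inhibitor CDKN1A by 1.98 (SE 0.15, adjusted p = 0.0253) and PPDPF by 1.93 (SE 0.10, adjusted p = 0.0253). CRIP1 (-1.60), the glycosyltransferase MFNG (-1.58), PPP1R27 (-1.57), SNRPN (-1.44), TARP (-1.34) and the protease inhibitor SERPINB6 (-1.34) followed. All of these were lower in every pair measured. Singly, gilteritinib lowered 46 genes and raised 0, crenolanib lowered 76 and raised 2, and AC220 lowered 33 and raised 1. These counts rest on the spread pooled over the inhibitors, and with only the compared libraries they were 13, 0 and 1. Without 1 of the inhibitor's own libraries they fell to as few as 1, 12 and 1. PPDPF, ELANE and CDKN1A led for gilteritinib, ELANE, CDKN1A and the metallothionein MT1E (-1.84, adjusted p = 0.02) for crenolanib, and CDKN1A, PPDPF and BEX1 (-1.55, adjusted p = 0.0296) for AC220.

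The libraries of the 3 MV4-11 replicates stood apart from each other before any inhibitor. In DMSO, FLT3 was at 11.5, 108 and 33.0 FPKM in replicates 1, 2 and 3, CDKN1A at 8.22, 103 and 23.8, PIM1 at 6.82, 83.5 and 21.0, and ELANE at 27.5, 425 and 112, while MYC was at 276, 267 and 352. Over the 29 called genes, the median ratio to replicate 2 in DMSO was 0.0838 in replicate 1 (28 genes) and 0.324 in replicate 3. Of the 335 genes at least 4-fold lower in DMSO of replicate 1 than of replicate 2, 18 were among the 29, and the median response of the 335 was -0.18, -0.78 and -0.39 in replicates 1, 2 and 3. Their choice by the DMSO levels of replicates 1 and 2 enters these responses, so the fall in replicate 2 is partly built in. Whether the choice also enters replicate 3, which was computed by subtraction of library 2, was not tested. Of the 1635 genes within 1.5-fold of each other there, 0 were among the 29, and their medians were -0.00, -0.07 and 0.03. Across 10170 genes, which are not independent replicates, the DMSO ratio of replicate 3 to replicate 2 correlated with the response of replicate 1, with which it shares no library (r = 0.448, rho = 0.439). After removal of transcript GC content and length, r was 0.466. The DMSO ratios themselves followed GC content, with rho = -0.541 for replicate 1 to replicate 2 and -0.291 for replicate 3 to replicate 2. A difference in library preparation may therefore account for part of these ratios.

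**Figure D3:**
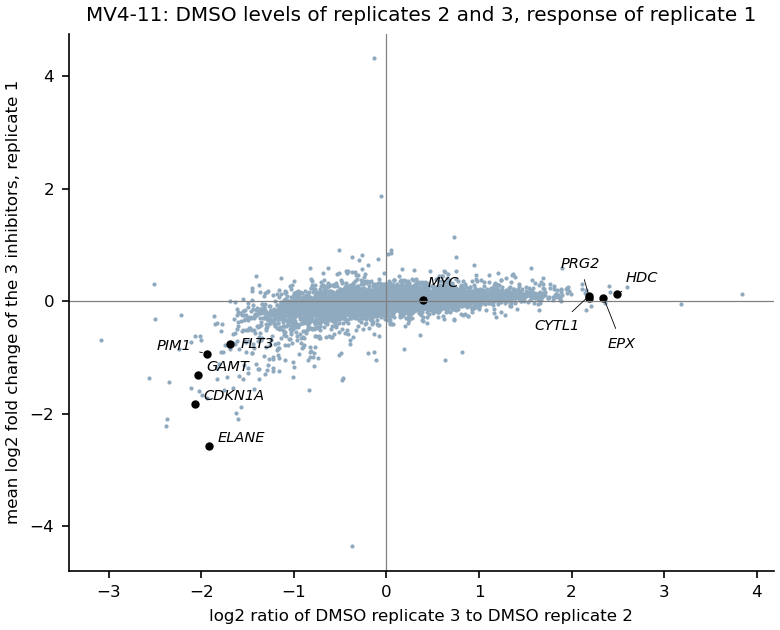
Each point is a gene of MV4-11, with the log2 ratio of DMSO replicate 3 to DMSO replicate 2 on the x axis and the mean log2 fold change over the 3 inhibitors in replicate 1 on the y axis. Genes low in DMSO replicate 3 (FLT3, CDKN1A, GAMT, PIM1, ELANE) lie to the left and below 0, and EPX, PRG2, CYTL1 and HDC, chosen after their values were seen, lie to the right (r = 0.448).

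The lists of MV4-11 moved less, and 12 of 27 were called with the preset and 0 with an estimated correlation. Fry called 1 of 27, the p53 targets (adjusted p = 0.0337). Of 15 p53 targets 1 fell, CDKN1A, with PHLDA3 at -1.09, TNFRSF10B at -0.88 and DDB2 at -1.21. The list had adjusted p = 6.44e-05, and 0.571 with an estimated correlation, and in DMSO its median ratio to replicate 2 was 0.433 in replicate 1 and 0.579 in replicate 3. Of 12 STAT5 targets 0 passed, with PIM1 at -2.29 ± 0.50 (SE, adjusted p = 0.274), SOCS3 at -0.82, CISH at -0.78 and SOCS2 at -0.53 (adjusted p = 0.00143 for the list, and 0.571 with an estimated correlation, with DMSO ratios of 0.517 and 0.666). Of 10 granule and progenitor markers 1 fell, ELANE, with PRTN3 at -0.87, AZU1 at -0.81 and CTSG at -0.58 (adjusted p = 0.0195, and 0.571 with an estimated correlation, with DMSO ratios of 0.240 and 0.592). Of 8 genes of the HOXA-MEIS1 programme 0 passed, with HOXA9 at -0.75, PBX3 at -0.66, MEIS1 at -0.62 and FLT3 at -0.56. That list had adjusted p = 0.0147, and 0.571 with an estimated correlation, with DMSO ratios of 0.221 and 0.473.

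Interferon response genes lay above 0 as a list in MV4-11 (adjusted p = 1.08e-05, and 0.571 with an estimated correlation) with 0 of 18 passing, MX1 at 0.62, OAS1 at 0.57, IFIT3 at 0.43 and IFIT1 at 0.42. In DMSO their median ratio to replicate 2 was 1.32 in replicate 1 and 2.45 in replicate 3. Of the markers of other cell types, the epithelial list was called and the lymphoid and erythroid lists were not. EPCAM was at 0.60, KRT18 at 0.30, KRT8 at 0.25 and PECAM1 at 0.15 (epithelial list, adjusted p = 0.0352, and 0.571 with an estimated correlation, with DMSO ratios of 1.18 and 1.75). CD3D was at 0.51, CD79B at 0.49, CD79A at 0.43 and NKG7 at -0.03 (lymphoid list, adjusted p = 0.0991, and 0.571 with an estimated correlation, with DMSO ratios of 1.90 and 2.72). GP1BB was at 0.71, GATA1 at 0.39, ITGA2B at 0.21 and EPOR at -0.60 (erythroid and megakaryocyte list, adjusted p = 0.174, and 0.628 with an estimated correlation, with DMSO ratios of 1.03 and 3.01). Histones also lay above 0 (adjusted p = 0.0352, and 0.571 with an estimated correlation), with HIST1H2AC at 1.41, HIST1H2BD at 0.99, HIST2H2BE at 0.58 and HIST2H2AC at -0.84. In DMSO their median ratio to replicate 2 was 107 in replicate 1.

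Cell cycle and metabolic lists lay slightly below 0 in MV4-11, with 0 members passing in each. The cell cycle lists were low mainly in replicate 2. In replicates 1, 2 and 3 the medians were -0.02, -0.60 and -0.08 for G1/S and -0.03, -0.73 and 0.01 for G2/M. The G1/S list (adjusted p = 0.000936, and 0.726 with an estimated correlation) had TK1 at -1.04, UHRF1 at -0.79, CCNE1 at -0.76 and CCNE2 at -0.63. The G2/M list (adjusted p = 0.00143, and 0.726 with an estimated correlation) had UBE2C at -2.90, MKI67 at -0.43, CDC25C at -0.44 and NUSAP1 at -0.39. The ATF4 list (adjusted p = 0.00834, and 0.726 with an estimated correlation) had CHAC1 at -1.22, CBS at -0.89, CEBPB at -0.54 and ATF5 at -0.37. The ATF4 medians were 0.09 and -0.02 in replicates 1 and 2 and -0.89 in replicate 3, whose DMSO library stood at 2.44 times that of replicate 2 in the median member. Oxidative phosphorylation had adjusted p = 0.0136, and 0.726 with an estimated correlation, with CYC1 at -0.55, UQCRFS1 at -0.43 and COX6C at -0.42. NF-kB and inflammatory genes had adjusted p = 0.00707, and 0.571 with an estimated correlation, with CXCL10 at -1.34, CCL2 at -1.26, TNFAIP3 at -0.46 and IL1B at -0.41.

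The other lists of MV4-11 were not called, and 0 of their members passed. MAPK output had FOS at -1.16, EGR1 at -1.28, IER3 at -0.79 and CCND1 at 0.45 (adjusted p = 0.804, and 0.888 with an estimated correlation), with a median of 0.01 and a mean of -0.15. FOXO targets had PIK3IP1 at 0.53 and PINK1 at -0.52 (0.694, and 0.882 with an estimated correlation), ribosome biogenesis BOP1 at -0.66 and FBL at -0.56 (0.523, and 0.888), and glycolysis GPI at -0.50 and PFKL at -0.38 (0.263, and 0.726). Arginine metabolism had SAT1 at 0.55 and SLC7A1 at -0.37 (0.755, and 0.888), cholesterol synthesis CYP51A1 at -0.60 and HMGCS1 at 0.30 (0.636, and 0.888), and heme and iron HMOX1 at 0.63 and FTL at -0.38 (0.419, and 0.844). Monocyte markers had HLA-DRA at 1.54, LYZ at -1.01 and FCGR1A at -0.82 (0.335, and 0.861), receptors KIT at 0.74 and AXL at 0.73 (0.419, and 0.861), and the BCL2 family BAX at -0.73 and BMF at 0.66 (0.112, and 0.571). Heat shock genes had HSPA1A at -1.15 and JUNB at -0.46 (0.907, and 0.941), with a mean of -0.08 and a median of 0.00, and ribosomal proteins RPS19 at -0.39 and RPL3 at -0.21 (0.254, and 0.861). Adjusted over the list alone, 5 HOXA-MEIS1 genes, 4 p53 targets, 4 granule markers, 3 STAT5 targets, 3 NF-kB genes, 3 monocyte markers, 2 MAPK genes and 1 each of the G2/M, receptor and erythroid lists fell. On the same footing 2 erythroid markers and 1 each of the granule, monocyte and receptor lists rose. Outside the creatine list, given above, the other counts were 0.

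The 29 calls of MV4-11 moved to 706 without replicate 1, 150 without replicate 2, 70 without replicate 3 and 0 without the AC220 library of replicate 2. Without the replicate as a block 0 genes were called for any inhibitor or their mean.

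No gene passed the joint test of differences among inhibitors in MV4-11 by limma, the only tool run (0 at an adjusted p under 0.05, 183 at an unadjusted p under 0.05). Without replicate 2 there were 15 such genes, and without its AC220 library 4. FLT3 was at -0.42 with gilteritinib, -0.83 with crenolanib and -0.43 with AC220, and the difference of gilteritinib and crenolanib was 0.42 (95% interval 0.03 to 0.80, adjusted p of the joint test 0.972). For GATM that difference was -0.03 (95% interval -0.27 to 0.22) and for GAMT -0.30 (-0.88 to 0.27). For the median gene the 95% interval reached 0.25 to 0.26 on either side. G1/S genes were higher with crenolanib than with AC220 as a list (median 0.16, adjusted p = 5.23e-06, and 0.762 with an estimated correlation). Fold changes of the inhibitors correlated across genes at 0.879 to 0.923, against 0.466 to 0.494 simulated with the shared controls, and their covariances were 0.0766 to 0.0924, against 0.00782 to 0.00787. Gilteritinib and crenolanib shared 45 falls, where independent lists would share 0.289, but the shared DMSO libraries alone would raise this overlap. Here too the simulated DMSO had only the spread seen between inhibitors, so the simulated values may be too low.

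The mean response differed between MOLM14 and MV4-11 for 3709 of 10908 genes, 1640 higher and 2069 lower in MOLM14. The count was 2373 without MV4-11 replicate 1, 1726 without MV4-11 replicate 3 and 1366 without the replicate as a block. The largest differences under the naming rule were those of the ETS factors ETV4 (-7.29 ± 0.25, SE, 2 against 3 replicates, adjusted p = 0.000161) and ETV5 (-6.15 ± 0.50), the telomerase gene TERT (-5.61), FERMT1 (-5.52) and the transporter SLCO4A1 (-5.50). These fell in MOLM14 and were at 0.30, 0.10, 0.36, 0.46 and -0.04 in MV4-11. In the other direction stood HMOX1 (4.12 ± 0.41, adjusted p = 0.00131), SPAG5-AS1 (3.99), the ubiquitin ligase MARCH1 (3.80), the metalloprotease MMP19 (3.76) and the prostaglandin D synthase PTGDS (3.61). Reads of SPAG5-AS1 could not be told from those of its sense partner. MYC differed by -3.98 (adjusted p = 0.000566), GATM by -1.82 ± 0.45 (adjusted p = 0.0224), FLT3 by 1.21 (adjusted p = 0.00432) and CDKN1A by 2.39 (adjusted p = 0.0013). The GATM difference rests in part on the pseudocount of 1, since GATM is low in MV4-11. With a pseudocount of 0.1 it was -1.40 and did not pass (adjusted p = 0.064), with GATM in MV4-11 at -1.46, and with a pseudocount of 5 it was -2.12 (adjusted p = 0.00557), with GATM in MV4-11 at -0.47. GAMT (0.53, adjusted p = 0.315), PIM1 (-1.20, adjusted p = 0.248), SLC6A8 (-0.34), CKB (0.29) and CKM (-0.08) did not pass.

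By list, 23 of 24 ribosome biogenesis genes were lower in MOLM14 (adjusted p = 6.03e-14, and 0.236 with an estimated correlation), as were 9 of 13 MAPK genes, with 1 higher (3.82e-05, and 0.229). The same direction was seen for 18 of 24 G1/S genes (1.72e-06, and 0.496 with an estimated correlation), 13 of 21 ATF4 targets (0.000476, and 0.536), 11 of 20 glycolysis genes with 1 higher (0.000266, and 0.229) and 8 of 19 cholesterol genes (0.000365, and 0.456). It was also seen for 10 of 15 arginine metabolism genes with 2 higher (0.00299, and 0.312 with an estimated correlation), 8 of 20 oxidative phosphorylation genes (0.00421, and 0.536), 6 of 14 heat shock genes (0.0145, and 0.466), 4 of 20 G2/M genes (0.0145, and 0.641) and 3 of 12 STAT5 targets with 1 higher (0.0486, and 0.536). In the other direction, 11 of 15 p53 targets with 1 lower (0.000365, and 0.404 with an estimated correlation), 8 of 14 FOXO targets with 1 lower (0.00371, and 0.404), 9 of 18 interferon genes (0.00404, and 0.536), 5 of 8 HOXA-MEIS1 genes (0.00187, and 0.362), 5 of 7 histones (0.000598, and 0.425) and 4 of 10 monocyte markers (0.037, and 0.536) were higher in MOLM14. Thus 17 of 25 lists were called with the preset and 0 with an estimated correlation. The rest were not, namely creatine (0.719), heme (0.404), granule markers (0.124), BCL2 family (0.697), NF-kB (0.474, median 0.70 and mean -0.25), receptors (0.0502), epithelial markers (0.594) and ribosomal proteins (0.0897). Adjusted over the list alone, 20 G1/S, 14 ATF4, 12 glycolysis, 11 cholesterol and 9 oxidative phosphorylation genes were lower, with 4 heme genes and 0 G2/M genes, and 9 FOXO targets, 6 histones, 5 NF-kB genes, 5 receptors and 1 heat shock gene were higher.

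Across the 10908 genes the mean responses of the lines, which share no library, correlated at 0.308 (rho = 0.307), and with single MV4-11 replicates at 0.0804, 0.390 and 0.116. The value of replicate 2 was raised by its AC220 library (0.563, against 0.305 for gilteritinib and 0.246 for crenolanib), which stood apart. The libraries of replicates 1 and 3 reached at most 0.171. Of 25 genes that fell in MV4-11 and were measured in both lines, 12 also fell in MOLM14, where independent lists would share 6.0, and 0 rose there. With MV4-11 replicate 2 alone, an alternative chosen after seeing the data, 807 genes differed between the lines in place of 3709. The spread then came from the MOLM14 replicates alone, so the loss of replicates enters this drop. The responses of MV4-11 replicates correlated at 0.433 (1 and 2), 0.580 (1 and 3) and 0.644 (2 and 3), and those of the MOLM14 replicates at 0.799.

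**Figure D4:**
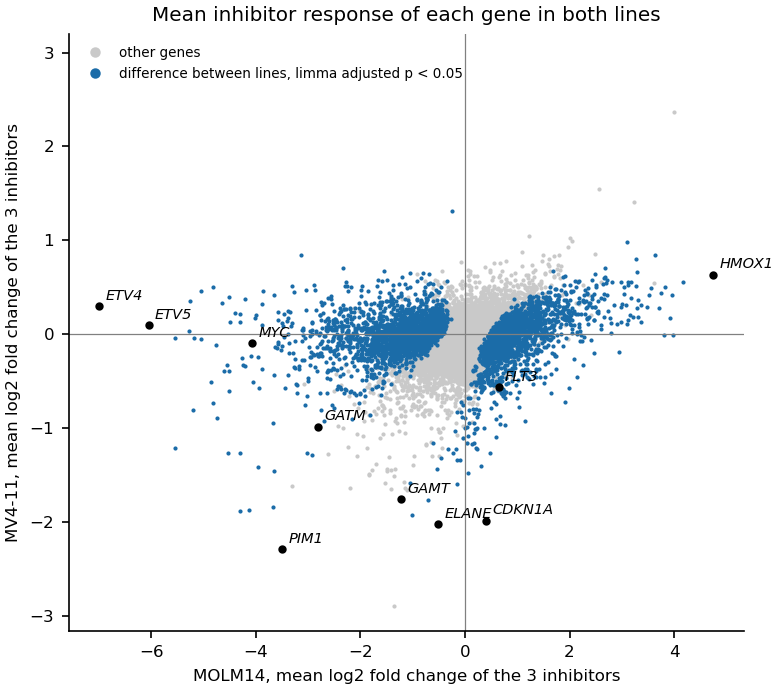
Mean log2 fold change over the 3 inhibitors in MOLM14 (x axis) and MV4-11 (y axis), a point per gene, with the 3709 genes whose difference passed in blue. ETV4 lies at -6.99 in MOLM14 and 0.30 in MV4-11, HMOX1 at 4.75 and 0.63, and the responses correlate at 0.308.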

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

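The tests of how many genes differ by grouping, of RNA without poly(A) tails, of GC content, of transcript length and of an AC220 effect were set out before their results were seen. The other tests in this part were chosen after the pattern had been seen. Intervals in this part are 95% ranges over resampled genes, which do not measure the spread between libraries.

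Genes of the MAPK, ATF4 and glycolysis lists and MYC fell in MOLM14 and hardly in MV4-11, apart from the ATF4 list in MV4-11 replicate 3 (median -0.89, with ASNS at -1.90 and CBS at -1.55). The STAT5 list, which shares MYC, was also lower in MOLM14 with the preset correlation (adjusted p = 0.0486, and 0.536 with an estimated correlation), and the difference of PIM1 did not pass (adjusted p = 0.248). The ETS factors of MAPK output ETV4 (difference -7.29) and ETV5 (-6.15), the telomerase gene TERT (-5.61), FERMT1 (-5.52), the transporter SLCO4A1 (-5.50) and the creatine synthesis gene GATM (-1.82) were lower in the MOLM14 response. The heme oxygenase HMOX1 (4.12), SPAG5-AS1 (3.99), the ubiquitin ligase MARCH1 (3.80), the metalloprotease MMP19 (3.76) and PTGDS (3.61) were higher in it. In all 3709 genes differed between the lines in the main fit, and 1366 without the replicate as a block, although both carry FLT3-ITD. When 1 library of each replicate, DMSO or an inhibitor, was taken as control, 3 of 100 choices, the real one among them, gave as many genes. The highest other count was 5459. Every choice still held inhibitor libraries, so what count would arise without an inhibitor was not tested. The tables of MOLM14 are in normalized counts and those of MV4-11 in FPKM, which cancels in ratios within a table but could shift the responses of low genes. GATM is such a gene, and with a pseudocount of 0.1 its difference was -1.40 and did not pass (adjusted p = 0.064).

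The weak MAPK, ATF4, glycolysis and MYC response of MV4-11 was set against 2 explanations. If cells that do not respond diluted replicates 1 and 3 alone, replicate 2 would show a response near that of MOLM14. The median log2 fold change of these genes in replicate 2 was 0.110 of the MOLM14 median (95% interval 0.00831 to 0.267, 41 genes), with MYC at -0.14 there against -4.07. The genes were list members with a called fall in MOLM14, and MYC by name, a choice that tends to lower the share. The interval covers resampled genes of 1 MV4-11 replicate. Its upper limit lay below the 0.5 that this explanation was taken to need and just above the 0.25 taken to exclude it. Both limits were set after the values were seen. For the genes so chosen, replicate 2 regained little of the response. Single genes, picked after their values were seen, went different ways in replicate 2. PIM1 (-3.73, against -3.49 in MOLM14), EGR1 (-2.78 and -2.63), IER3 (-1.23 and -1.21) and CISH (-1.60 and -1.67) were as low as in MOLM14, while ETV4 (0.56), ETV5 (0.16) and SPRY2 (0.33) lay above 0. If FLT3 was inhibited less in MV4-11, its STAT5 targets would also fall less there than in MOLM14. The share of those that fell in MOLM14, chosen in the same way, was 0.355 in replicate 2 (0.104 to 1.02, 7 genes), too wide to decide. An antibody measurement of phosphorylated FLT3, STAT5 and ERK in both lines at this dose would show whether it was.

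The replicates of MV4-11 differed in the size of the response for genes called with replicate 2, with slopes on replicate 2 of 0.230 for replicate 1 (602 genes called without replicate 1) and 0.642 for replicate 3 (SE 0.0386, 70 genes called without replicate 3). Choosing genes with replicate 2 favours that replicate. Over the 150 genes called without replicate 2 the medians were -0.81, -0.91 and -0.92 in replicates 1, 2 and 3, a ratio of replicate 3 to 2 of 1.01, so the size of the difference rests on the genes chosen. FLT3, CDKN1A, PIM1, GAMT and ELANE were each lower in DMSO of replicates 1 and 3 than of replicate 2. Cells that do not respond would lower the DMSO level of the HOXA-MEIS1 programme and the change of the responding genes by the same share. In replicate 3 that level was 0.473 of that of replicate 2 (0.304 to 1.30, 8 genes), and the median linear change of the 70 genes was 0.295. In replicate 1 the level was 0.221 (0.106 to 2.26, 5 genes) and the median change of the 602 genes 0.0772. The levels spread too widely, and the choice of genes lowers the changes, so neither could be decided. Whether the gene models of the table of replicate 1 play a part could not be decided either, since the slope of replicate 3, with the usual models, depends on that choice. The median histone gene stood in replicate 1 at 107 times its level in replicate 2 (32.4 to 425, 8 genes). In replicate 3 that ratio was 0.623. A high ratio was the outcome set beforehand for more RNA without poly(A) tails in replicate 1, though it rests on 1 list and other gene models. Whether such RNA made the response of replicate 1 smaller was not tested.

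Cells of another expression profile, in shares that differ between replicates and rise with the inhibitors, are a candidate explanation that was found from these values and not tested apart from them. Genes at least 2-fold higher in DMSO of replicate 3 than of replicate 2 had a median response in replicate 1 that lay 0.306 above that of genes at least 2-fold lower (0.281 to 0.365, 157 genes not called in MOLM14). Replicate 1 shares no library with that ratio, but this restates the correlation that prompted it. The same sign would arise if FLT3 output was lower in the DMSO cultures of replicates 1 and 3 and fell further with inhibitors, so a state of the line itself may explain it as well. The DMSO ratio of replicate 3 to replicate 2 also followed transcript GC content (rho = -0.291), so library preparation may enter the DMSO levels too. Short tandem repeat profiles or single-cell sequencing of these cultures would separate cells of another profile from a state of the line. Until then the low GATM and GAMT of MV4-11 cannot be placed in either.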

How the results depend on the processing

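The alternatives were set out before the data were examined, apart from those named as added, which were chosen after the data had been seen. The added ones include a separation scale 2% lower or higher, another separation of the averaged tables and a spread of its own in each line, under which every count stayed within 1.5 times. No named result that was called in the main fit changed sign in any of them. Of the named MV4-11 values that were not called there, 9 changed sign under an alternative. The DESeq2 and voom fits were not run, since no table holds counts of all libraries. GATM in MOLM14 stayed between -3.28 and -2.34 with any replicate or library left out.

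With the replicate not entered as a block, 3115, 3448 and 2435 genes passed for gilteritinib, crenolanib and AC220 in MOLM14, 0, 0 and 0 in MV4-11, 0 for the MV4-11 mean and 1366 for the lines. The pairing therefore carried every MV4-11 call, and ELANE and CDKN1A were called through it.

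A log2 fold change of at least 1 in addition left 2566, 2795, 2328 and, for the mean, 3016 genes in MOLM14, 44 for crenolanib in MV4-11 and 2023 for the lines. Quantile normalization gave 6 genes that differ among inhibitors in MOLM14 and 14 for AC220 in MV4-11. Without a filter 46 genes differed among inhibitors in MOLM14, and with a stricter filter, which drops GATM in MV4-11, 77. With a pseudocount of 0.1, MV4-11 had 75 genes for gilteritinib, 118 for crenolanib and 19 for the mean. With a pseudocount of 5 it had 9, 12 and 8 for the inhibitors and 0 for the mean. GATM in MV4-11 was at -1.46 and -0.47 with these, and its difference between the lines at -1.40, which did not pass, and -2.12. With only the compared libraries it had 13, 0 and 1. With an estimated correlation 0 lists passed in MOLM14 and 0 in MV4-11, in place of 18 and 12.

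The fit of all libraries with the replicate as a block, added and seen before the main analysis was settled, gave 80, 139, 52 and, for the mean, 221 genes in MV4-11 and 5881 for the lines. GATM in MV4-11 was at -0.99 and passed (adjusted p = 0.0198) there. The deposited tables taken as replicates, also added, gave 10385, 10421, 9991 and 9861 genes in MOLM14, 3813 that differ among inhibitors there, 714, 809 and 272 in MV4-11 and 6712 for the lines. These tables share libraries, so such counts are too high. MV4-11 replicate 2 alone, also added, left 807 for the lines.

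With a library or replicate left out, the MOLM14 counts ran from 623 to 4377 for gilteritinib (623 and 2662 without its own library of replicate 1 and 2), from 885 to 4899 for crenolanib (885 and 2560) and from 641 to 3847 for AC220 (808 and 641). The mean ran from 4795 to 5584. From 0 to 20 genes differed among inhibitors, the 20 without gilteritinib of replicate 2.

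In MV4-11 the mean ran from 0 to 707. It was 706 without replicate 1 (707 without its DMSO, 18 without its gilteritinib), 150 without replicate 2 (164 without its DMSO, 0 without its AC220) and 70 without replicate 3 (70 without its DMSO, 9 without its AC220). GATM ran from -1.31 to -0.73, and passed at -1.31 without replicate 1 (adjusted p = 0.000222).

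Single inhibitors in MV4-11 ran from 0 to 97 for gilteritinib, 0 to 88 for crenolanib and 0 to 109 for AC220. Without replicates 1, 2 and 3 they gave 3, 83 and 0 for gilteritinib, 1, 88 and 0 for crenolanib and 1, 100 and 0 for AC220. Without the DMSO libraries they gave 1, 97 and 0, then 1, 88 and 0, then 1, 109 and 0. Without their own inhibitor libraries they gave 2, 6 and 1, then 32, 12 and 27, then 1, 21 and 1. Without gilteritinib of replicate 3, crenolanib gave 48. AC220 gave 16, 17 and 15 without gilteritinib of replicates 1, 2 and 3 and 21 without crenolanib of replicate 3. From 0 to 15 genes differed among inhibitors, 15 without replicate 2 and 4 without its AC220.

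The lines differed for 1722 to 4328 genes, with 2373 without MV4-11 replicate 1 (2378 without its DMSO) and 1726 without replicate 3 (1722 without its DMSO). Among the alternatives for named genes, 2821 of the MOLM14 results were the same, 25 weaker, 9 stronger and 29 moved, against 2975, 154, 188 and 9 in MV4-11, and 400, 18, 0 and 0 for the lines.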

Other observations

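The tests on GC content, transcript length, an AC220 effect and all groupings were set out before their results were seen, and the test on MOLM14 RNA was chosen after. The eosinophil, basophil and progenitor genes named here were chosen after their values were seen. Intervals of correlations here are ranges over resampled genes as well.

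Several genes known from eosinophils, basophils and progenitors differed between the MV4-11 replicates in DMSO, as single genes and not as a tested list. The granule proteins EPX (88.9, 8.02 and 44.8 FPKM in replicates 1, 2 and 3) and PRG2 (399, 61.3 and 284), the histidine decarboxylase HDC (79.3, 18.9 and 111) and the transcription factor GATA2 (33.1, 6.15 and 19.9) were lowest in replicate 2. CYTL1 (1121, 11.8 and 57.1), of CD34-positive cells, and COCH (78.8, 15.7 and 58.0) were also lowest there. Their mean responses in MV4-11 were 0.52, 0.65, 0.54, 0.38, 0.88 and 0.61 for EPX, PRG2, HDC, GATA2, CYTL1 and COCH, and none passed. In MOLM14, PRG2 (-1.06), GATA2 (-2.56) and COCH (-1.20) fell, EPX was at 0.07 and did not pass, and CYTL1 and HDC had no value. Staining of the cultures for PRG2 or EPX would show whether all cells carry them.

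The ATF4 and serine synthesis list had its lowest median among the MV4-11 replicates in replicate 3, at -0.89, against 0.09 and -0.02 in replicates 1 and 2. The replicates were not tested against each other, and 0 of 21 members passed. CBS was at -1.11 in replicate 2 and -1.55 in replicate 3, PSAT1 at -0.35 and -1.28, and ASNS at -0.27 and -1.90. The list stood higher in DMSO of replicate 3 than of replicate 2, at a median of 2.44 times.

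The AC220 library of MV4-11 replicate 2 stood apart from the gilteritinib and crenolanib libraries of that replicate. Its log2 ratio to them correlated with transcript GC content (rho = 0.443, 0.429 to 0.460, 11433 genes, and -0.22 for gilteritinib against crenolanib), so a difference in library preparation may account for part of it. Transcript length (0.133, 0.113 to 0.153, and -0.24 for gilteritinib against crenolanib) did not decide. RNA of MOLM14 in that library could be tested with 1 gene only (-0.26). An effect of AC220 itself would recur in replicate 3, but the ratios of replicates 2 and 3 correlated at -0.41. Those of replicates 2 and 1 correlated at 0.0317. The subtraction of library 2 from the mean of libraries 2 and 3 may contribute to the -0.41, which was not measured. The log2 ratio of the AC220 library of replicate 2 also correlated with the MOLM14 response (0.376, and 0.448 after removal of GC content and length). For gilteritinib against crenolanib that correlation was 0.167.

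The counts were set beside groupings of libraries other than the real one. All of these still held inhibitor libraries, so they do not show what counts would arise without an inhibitor. For the mean response of MV4-11, 1 of 64 choices of a control per replicate, the real one, gave 29 genes, and the highest other gave 22. An inhibitor library as control keeps part of the effect with the opposite sign, so lower counts are partly built in. With 6 libraries and the replicate as a block, 3 of 10 splits gave at least the 13 genes of gilteritinib (highest other 3219), 10 of 10 the 0 of crenolanib (3428) and 3 of 10 the 1 of AC220 (1981). With 10 splits no share can fall under 0.05, and a real count of 0 makes 10 of 10 certain, so these are too few to decide. A split that puts both libraries of a replicate on 1 side takes its difference from 1 other replicate alone, since the block absorbs the rest. There the difference is the real one of inhibitor and DMSO, so such a split does not show a count without an inhibitor effect. Which splits gave the highest counts is not given here. For differences among inhibitors in MV4-11, 36 of 36 relabellings gave as many genes as the real 0, with 0 as the highest other, which a real count of 0 makes certain, so nothing can be read from it.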
